A study of Schmidtea mediterranea with 162 samples.

How the data were processed

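The series holds 162 samples of Schmidtea mediterranea: 160 single cells on 2 plates (40 X1 and 40 Xins cells on each) and 2 droplet libraries. Each plate cell was placed in its group by its title, the X1 droplet library by its source name and the irradiated one by its treatment label. Per the submitters' processing notes, bcl2fastq 2.18, Bowtie2 2.2.9 and SAMtools were used, without a statement of role or order, and the transcriptome and counting method are not given in the sources used here. Per the labels' protocols, plate libraries were made with SMART-Seq v4 and Nextera XT and sequenced on an Illumina HiSeq, with no molecular identifiers.

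The deposited plate tables hold whole-number read counts of 36035 transcript IDs in each cell, as the values show; the authors' table of each plate also has columns that match no sample, 14 in all, and these were not used. The deposited droplet tables hold natural log values per cell, and no label states how they were made. Their inverse, exp(value) - 1, sums to a median of 59996 per X1 library cell and 59948 per irradiated cell, so the values fit the natural log of 1 plus UMIs scaled to 60000 per cell. Within a cell the unlogged values are multiples of 1 step, and 99.98% of the values of the X1 library and 99.99% of those of the irradiated library came within 0.1 of a whole number, so whole UMIs were recovered from them. The UMI totals per cell are therefore this reconstruction, checked on 414487 simulated values, of which 100% were recovered. The tables list 27525 IDs for the X1 library and 21368 for the irradiated library, with 20419 in both, 7106 in the former alone and 949 in the latter alone. An ID listed in 1 table was taken as 0 in the other, and single IDs were printed from those in both.

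On each plate, cells with at least 500 IDs with a read and 10000 reads were kept, which kept all 160. Reads were summed per population and plate, scaled to a total of 1000000 (CPM), and log2 folds were taken with a pseudocount of 1 CPM. The size rule asked for 20 CPM in 1 population of each plate, a read in at least 20% of the cells of the higher population, and a log2 fold of at least 1 in the same direction on both plates. On simulated counts over 36035 IDs for this comparison, the rule took up 28.4% of 67 IDs set 2-fold apart, 83.6% of 67 set 4-fold apart and 95.5% of 66 set 8-fold apart, and 155 of 4367 IDs with no difference. The changed IDs were picked from those well above the rule's CPM and cell limits in the ClonTechv4 Xins cells. Both populations were drawn from Xins values, so the rates do not cover IDs near these limits or nearly absent from Xins. IDs were ranked by the smaller of the plates' absolute folds, and the 2 best-ranked in each direction were printed; since the files pair no ID with a gene name, 0 members of the 25 lists fixed beforehand were matched, and the planned list results were replaced by the X1-high and Xins-high sets, a choice made after the files were seen. Depth varied between wells, so IDs per cell were also counted after thinning to 500000 reads.

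The droplet comparison used cells with at least 200 IDs, which left out none, UMIs summed per library, a pseudocount of 10 CPM, and IDs with at least 100 UMIs over both libraries. Folds on this scale understate the difference of low IDs. A set's median was placed among 10000 random lists of the same size matched in 20 bins of mean expression. Set shares were taken over UMIs outside the dominant ID. Clusters came from scanpy 1.11.5 with python-igraph 0.11.9 (scaling to 10000, log1p, 2000 variable IDs, 30 principal components, 15 neighbours, Leiden resolution 1, seed 0), for the X1 library alone and for both libraries with no correction for library. Joint clusters with under 10% irradiated cells are called led by the X1 library and those with over 90% irradiated-led. With 1039 irradiated cells beside 7088 X1 library cells, the limit of 10% lies near the overall mix and that of 90% far from it. These limits, the 5% point of the X1 library and the 15% value were chosen after seeing the data. Plate cells were matched to the joint cluster of highest Spearman correlation over 2000 variable IDs, also a choice made after seeing the data. The joint clustering was repeated after limiting each cell to 4000, 9000 and 16000 UMIs. Each depth was thinned once and clustered with 6 seeds, so the seeds do not cover the random thinning. Scrublet called 1 of 7088 X1 library cells and 2 of 1039 irradiated cells doublets. For the X1 library this is too few for the caller to have worked, so doublets were left in and remain possible.

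No test between groups was made, since each population on a plate and each droplet library is 1 sample and the 2 plates were kept apart. Intervals are 95% exact Poisson for sums and 95% Clopper-Pearson for shares, and cover counting error only. Alternatives covered cell filters, TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0 (used for scaling only), means over cells, pseudocounts, minimum levels, summed plates, thinning, clustering settings and random seeds, with others added after seeing the data. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and R 4.3.3.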

Results

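RNA of single cells was sequenced from the freshwater planarian Schmidtea mediterranea, a flatworm that rebuilds lost body parts from dividing stem cells called neoblasts. Cells were sorted by flow cytometry into X1, the irradiation-sensitive cycling fraction in which neoblasts are found, and Xins, the irradiation-insensitive fraction. On 2 plates, named here by their label prefixes ClonTechv4 and Mantis, 40 X1 and 40 Xins cells each were taken from animals 3 days after amputation and prepared with SMART-Seq v4. The design text describes one batch of full-size and one of reduced-size reactions, whereas the extraction protocol gives the recommended volume for all, so the reaction volume of each plate was left open. Droplet (10x) libraries were made from X1 cells of untreated animals and from cells of the X1 and X2 gates together, taken 7 days after a sublethal dose of 1250 rad.

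The summed reads on transcript identifiers (IDs) were 128576428 for X1 and 105733799 for Xins on the ClonTechv4 plate, and 125272191 and 118184285 on the Mantis plate. The median per cell was 3318222 and 2797410 reads on the first plate and 3053116 and 2947383 reads on the second, and the shallowest well, an X1 well of the ClonTechv4 plate, held 20390 reads. The X1 droplet library held 7088 cells with a median of 16278 unique molecular identifiers (UMIs) per cell, and the irradiated X1+X2 library held 1039 cells with a median of 9080. No label named an animal, culture or donor, so each sorted population on a plate and each droplet library counted as 1 sample. No test between groups was therefore made, values of both plates are given side by side, and intervals cover counting error only, which for plate reads without UMIs leaves out amplification error.

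The first question was what sets the X1 fraction apart from the Xins fraction. X1 cells held reads of more IDs than Xins cells on both plates. The median was 6041 against 4189 IDs with a read on the ClonTechv4 plate and 6205 against 4223 on the Mantis plate. After every cell was thinned to 500000 reads, which left out 1 X1 cell of the ClonTechv4 plate, the medians were 5240 against 3610 and 5279 against 3552. The median pairwise correlation of log2 values was 0.44 and 0.48 for X1 cells and 0.26 and 0.28 for Xins cells, which was not separated from the number of IDs per cell. The Xins well numbered 9 held reads of 17202 IDs on the ClonTechv4 plate and of 17197 on the Mantis plate, whereas no other Xins well exceeded 5746 and 6686.

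**Figure D1:**
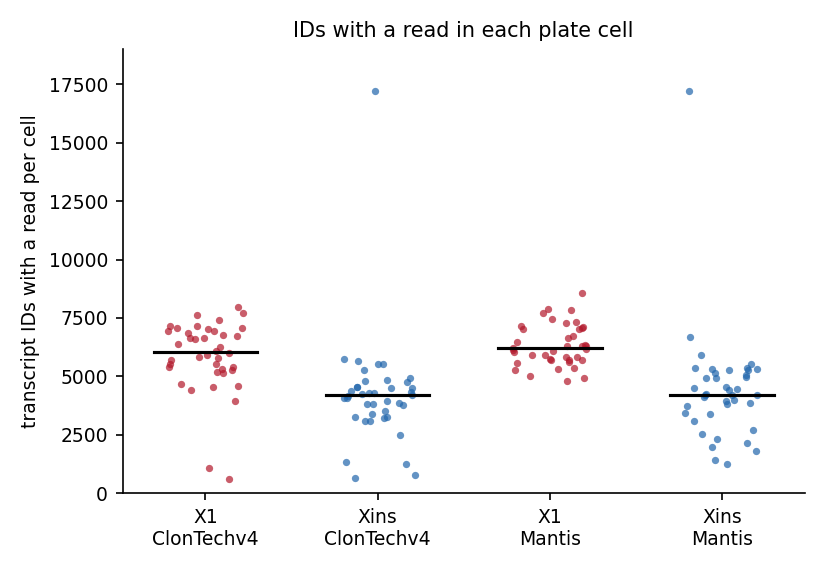
Number of transcript IDs with at least 1 read (vertical axis) in each of the 40 cells of X1 (red) and Xins (blue) on each plate (horizontal axis), points spread sideways for legibility, with the median of each group as a bar. The X1 medians of 6041 and 6205 lie above the Xins medians of 4189 and 4223, and the Xins well numbered 9 stands alone near the top on both plates.

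A single ID, SMED30032887, singled out after its values were seen, took a large share of the reads in every population. It held 52.0% of X1 reads and 43.3% of Xins reads on the ClonTechv4 plate, and 48.6% and 36.8% on the Mantis plate. The share varied more among Xins cells, where its quartiles were 26.4% and 55.0% on the first plate and 16% and 48.2% on the second, than among X1 cells, where they were 48.4% and 55.3%, and 45.0% and 51.5%. In the droplet data it held 54.7% of the UMIs of the X1 library and 34.9% of those of the irradiated X1+X2 library.

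By the size rule fixed before the data were examined, 1051 IDs were higher in X1 and 1088 higher in Xins (at least 2-fold on both plates, 20 CPM (reads scaled to a total of 1000000) in 1 population of each plate, and a read in at least 20% of the cells of the higher population). These are called the X1-high and the Xins-high set. The choice of the sets on these reads makes each take a higher share in its own population, so the shares describe size alone. The X1-high set took 24.9% and 27% of the X1 reads outside the dominant ID on the 2 plates, against 5.5% and 5.3% of the Xins reads. The Xins-high set took 21.4% and 26.9% of the Xins reads and 4.3% and 4.3% of the X1 reads. Leaving the dominant ID out of the totals, a choice made after its share was seen, gave 1774 IDs higher in X1 and 1032 higher in Xins, so that 63.2% of the IDs past the rule lay towards X1 in place of 49.1%.

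The sets differed in how widely single cells shared them. This was not separated from the higher number of IDs per X1 cell, which by itself raises the share of X1 cells with a read. An ID of the X1-high set had a read in a median of 62.5% of X1 cells on the ClonTechv4 plate and 72.5% on the Mantis plate. An ID of the Xins-high set had a read in a median of 35% and 41.25% of Xins cells. In the X1-high set, 30% and 42.7% of the IDs had a read in at least 80% of the X1 cells, whereas 4.0% and 6.1% of the Xins-high IDs reached that breadth among Xins cells. The median CPM in the higher population was similar, at 55.2 and 63.5 for the X1-high set and 61.9 and 74.9 for the Xins-high set.

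None of the members of the 25 gene lists fixed beforehand could be matched, since the files give IDs without gene names, so IDs are printed as they stand. The X1-high ID ranked first by the smaller of the plates' folds, SMED30004304, had 324 CPM in X1 (95% Poisson interval 321 to 327) and 0.180 CPM in Xins (0.108 to 0.281) on the ClonTechv4 plate, and 450 CPM (446 to 454) against 0.245 CPM (0.164 to 0.352) on the Mantis plate. It had a read in 38 and 40 of the 40 X1 cells, and in 1 and 4 of the 40 Xins cells. Its 19 and 29 Xins reads came mostly from the well numbered 9, so its Xins values and their intervals rest mostly on that well. Without that well its log2 folds were higher, at 8.34 and 8.78. The next, SMED30030946, had 191 and 220 CPM in X1 and 0.0567 and 0.271 CPM in Xins, with a read in 31 and 40 X1 cells. Its 6 and 32 Xins reads also came mostly from the well numbered 9. Without that well its log2 folds were 7.56 and 7.79 in place of 7.51 and 7.44. At the other end, SMED30002634 had 961 CPM (956 to 967) and 1234 CPM (1228 to 1240) in Xins against 0.0156 CPM (0.00188 to 0.0562) and 0.0239 CPM (0.00494 to 0.0700) in X1, which rest on 2 and 3 reads. Its Xins reads came from 8 of the 40 cells on each plate (20.0%, exact binomial interval 9.05% to 35.6%). That share is exactly the lower limit of the size rule. The well numbered 9 was among these cells on both plates, so without that well this ID falls short of the rule. Its log2 folds without that well were -9.90 and -10.26, in place of -9.89 and -10.24. SMED30014482 had 526 and 456 CPM in Xins, from 10 and 11 of the 40 cells, and 3 reads among the X1 cells of each plate.

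The X1-to-Xins folds of the plates followed each other across IDs. Over the 5940 IDs with 20 CPM in 1 population of each plate, Pearson's r of the log2 folds was 0.86 and Spearman's rho 0.83, as a description across IDs, which are not replicates, and 82.6% of the IDs had the same sign. At least a 2-fold difference in the same direction on both plates was found for 2532 IDs and in opposite directions for 61. The median log2 fold of all 5940 IDs was -0.13 on the ClonTechv4 plate and -0.06 on the Mantis plate. With a minimum of 100 CPM r was 0.95, and with no minimum 0.62.

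**Figure D2:**
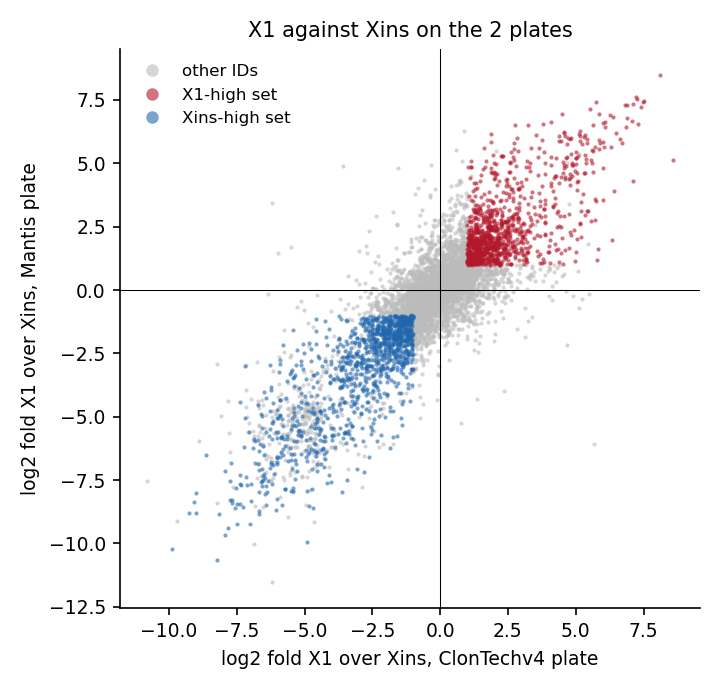
Log2 fold of X1 over Xins on the ClonTechv4 plate (horizontal axis) against the Mantis plate (vertical axis), 1 point per ID, for the 5940 IDs above the CPM minimum. The 1051 X1-high IDs (red) and 1088 Xins-high IDs (blue) passed the size rule on both plates, and r over the IDs shown was 0.86.

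The droplet libraries addressed which cells remained 7 days after sublethal irradiation. The irradiated library differs from the X1 library in its gate (X1+X2 against X1) as well as in the irradiation, and this holds for each value that follows. The X1-high set of the plates was lower in the irradiated X1+X2 library, with a median log2 fold of -1.04 over its 1042 measured IDs, of which 1012 were lower and 30 higher. The Xins-high set was higher, with a median of 1.31 over 1051 IDs, of which 1035 were higher and 16 lower. Among 10000 random lists matched on mean expression, the median lay at percentile 0 for the X1-high set (95% of the random medians between 0.08 and 0.25) and at percentile 100 for the Xins-high set (0.15 to 0.31). The random lists vary IDs as if independent, whereas the IDs of a set were chosen together. The percentiles thus describe these 2 libraries and measure no spread between libraries. The median over all 16899 IDs with at least 100 UMIs was 0.13, and -0.05 with the dominant ID left out, where the sets stood at -1.62 and 1.22.

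Single IDs spanned a wider range. SMED30013976 had 0.722 CPM (Poisson interval 0.580 to 0.889) in the X1 library and 2026 CPM (2002 to 2050) in the irradiated X1+X2 library, with a UMI in 1.20% and 44.1% of the cells. SMED30005838 had 51.9 CPM against 9101 CPM, with a UMI in 10.8% of X1 library cells and 94.0% of irradiated cells. Both lay outside the plate-defined sets, and few cells held most of their UMIs: 50 cells of 1 joint cluster held 97.7% of the irradiated library's UMIs of SMED30013976, and 187 cells of 2 joint clusters held 96.8% of those of SMED30005838. The IDs with the lowest folds, SMED30031235 and SMED30007406, belonged to the X1-high set. SMED30031235 had 826 CPM (821 to 832) against 47.2 CPM (43.6 to 51.0), with a UMI in 99.2% (98.9% to 99.4%) and 5.87% (4.52% to 7.48%) of the cells. SMED30007406 had 1412 CPM against 115 CPM, with a UMI in 99.7% and 9.82% of the cells. Of their UMIs in the irradiated library, 89.5% and 89.4% lay in joint cluster 16 with 105 irradiated cells. Over the 4 joint clusters with 10% to 90% irradiated cells, the log2 folds were 2.44 for SMED30013976, 4.65 for SMED30005838, -5.64 for SMED30031235 and -6.12 for SMED30007406, in place of 7.57, 7.20, -3.87 and -3.51. There, 93 of the 139 X1 library cells lay in cluster 15 and 147 of the 200 irradiated cells in cluster 11. These folds therefore also compare different clusters and are no comparison within a cluster. After thinning to 4000 UMIs per cell, the shares in the X1 and the irradiated library were 0.240% and 21.7% for SMED30013976, 2.5% and 80.8% for SMED30005838, 93.8% and 3.66% for SMED30031235, and 98.1% and 5.77% for SMED30007406. No cell class that should lack an ID could be named here, so shares of cells with a UMI can include free RNA, also where the share is high and few cells hold most of the UMIs.

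Cell by cell, the irradiated X1+X2 library lay mostly apart from the X1 library. The X1-high set took a median of 25.9% of a cell's UMIs outside the dominant ID in the X1 library (5% to 95% range 23.3% to 28%) and 5.69% in the irradiated library (2.38% to 12%). The Xins-high set took 4.67% (3.83% to 6.06%) and 20.2% (7.77% to 38.3%). Thinning to 2000 UMIs outside the dominant ID left the X1-high medians at 25.9% and 5.65%. At or above the lower 5% point of the X1 library lay 28 of 1039 irradiated cells, or 2.69% (exact binomial interval 1.80% to 3.87%), and 1 irradiated cell lay within 2 percentage points of that limit. These 28 cells had X1-high shares of 23.6% to 28.5% and a median Xins-high share of 4.82%, beside 4.67% in the X1 library and 21.1% in the other irradiated cells. Another 12 irradiated cells lay between 15% and 19.1%. The limit is a range of a score, not a cell type.

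**Figure D3:**
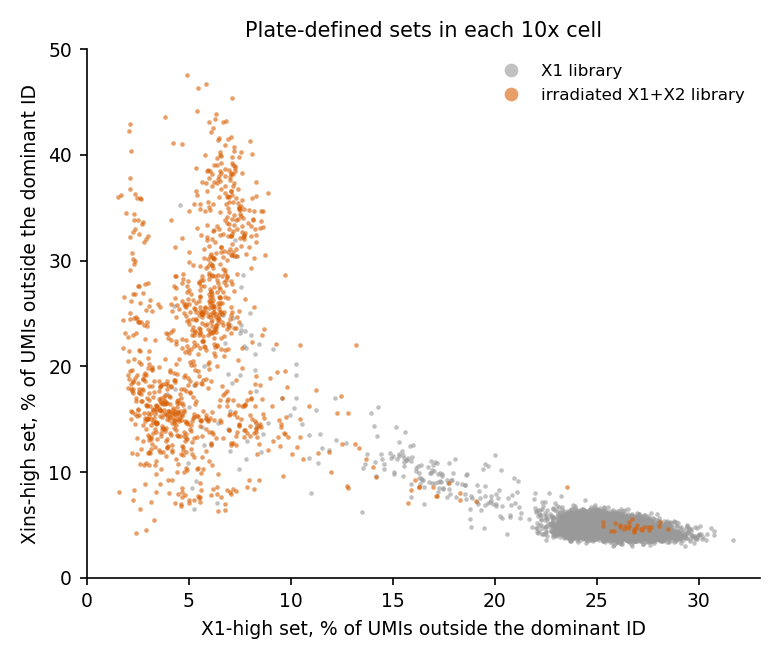
Share of each droplet cell's UMIs outside the dominant ID taken by the X1-high set (horizontal axis, percent) and by the Xins-high set (vertical axis, percent), 1 point per cell, for 7088 X1 library cells (grey) and 1039 irradiated X1+X2 library cells (orange). Of the irradiated cells, 28 lie among the X1 library cells on the right, and the others extend up to an Xins-high share of 47.6%.

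Genes per cell depended on the depth and on the dominant ID. The median was 3084 IDs with a UMI in the X1 library and 2280 in the irradiated X1+X2 library at full depth. Thinned to 4000 UMIs per cell, the order turned, with 1140 against 1274 IDs. Thinned to 2000 UMIs outside the dominant ID, which left out 7 X1 library cells and 1 irradiated cell, it was 1239 against 1051.

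Clustering asked which classes of cells the X1 fraction holds. The 7088 X1 library cells fell into 14 clusters, which carry numbers by size here, since no marker could be matched to name them. The 6 most populous held 19.3%, 18.3%, 15.8%, 13.5%, 12.7% and 9.95% of the cells, and their median X1-high shares lay between 24.9% and 26.6%. Their median UMIs per cell ran from 11776 to 22771, and depth was not separated from these clusters. Among IDs with a UMI in at least 50% of a cluster's cells, none was 8-fold higher than elsewhere in clusters 3, 5, 6, 8 and 9. These clusters need not be classes of cells. The 4 least populous, clusters 11 to 14 with 96 cells in all, had median X1-high shares of 15.5%, 8.01%, 14.2% and 6.95%. Over the whole library, 85 cells, or 1.20% (0.959% to 1.48%), had an X1-high share under 15%, with 60 cells within 2 points of that value. Their median Xins-high share was 15.4%. The number of clusters ranged from 9 to 22 over the alternatives, and the adjusted Rand index to the main clustering from 0.60 to 0.92. The most populous cluster held 13.5% to 34% of the cells over these alternatives.

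Clustered together, the libraries separated. Of 21 joint clusters, 10 were made up of X1 library cells by over 90% and held 97.6% of the X1 library (97.2% to 98.0%) and 0.87% of the irradiated X1+X2 library (0.40% to 1.64%). In 7 clusters over 90% of the cells came from the irradiated library; they held 79.9% of its cells (77.3% to 82.3%) and 0.42% of the X1 library. The remaining 4 mixed clusters held 1.96% of X1 library cells and 19.2% of irradiated cells. With 1 library of each kind, a cluster mostly of 1 library can be that library and not a cell type, so cluster sizes were not compared further. The joint clusters were less stable than those of the X1 library alone, with an adjusted Rand index of 0.21 to 0.73 over the alternatives and of 0.60 to 0.73 over 5 other seeds. With cells thinned to 4000 UMIs, clusters led by the X1 library held 2.31% of the irradiated cells, and 3.37% to 4.62% under 5 other seeds.

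The plate cells were then matched to these clusters by Spearman correlation. The best correlation had a median of 0.25 and 0.28 for X1 cells and 0.30 and 0.38 for Xins cells on the ClonTechv4 and Mantis plates. Each cell was given its best cluster however small the lead over the next, which the intervals below leave out. Of the 40 X1 cells, 40 on the ClonTechv4 plate and 38 on the Mantis plate matched best to a cluster led by the X1 library (exact binomial intervals 91.2% to 100% and 83.1% to 99.4%). Of the 40 Xins cells, 3 and 1 did so (1.57% to 20.4% and 0.06% to 13.2%). Irradiated-led clusters took 21 of the 40 Xins cells on the ClonTechv4 plate and 35 on the Mantis plate, and mixed clusters took 16 and 4. The clusters came from the X1 and the irradiated X1+X2 library alone, with no library of Xins cells. A plate cell unlike X1 cells could hardly match other than irradiated-led or mixed clusters. These matches therefore show no likeness of Xins cells to irradiated cells as such. With Pearson correlation, added after seeing the data, 37.5% of the ClonTechv4 Xins cells matched clusters led by the X1 library, in place of 7.5%, and 12.5% of the Mantis Xins cells, in place of 2.5%. With 1000 variable IDs the shares were 15% and 0%. Of the X1-high IDs, 88.5% had their highest cluster mean in a cluster led by the X1 library, against 2.85% of the Xins-high IDs. The share over all measured IDs was not computed, so how far either set departs from other IDs is not known.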

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

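The tests in this part were chosen after the results were seen.

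The plates disagreed in direction for 61 IDs, each at least 2-fold higher in X1 on one plate and at least 2-fold higher in Xins on the other. The difference between the plates was not tested. On the plate in question the higher population had a read of such an ID in a median of 27.5% of its cells on the ClonTechv4 plate and 30% on the Mantis plate, beside 42.5% and 50% for the 2532 IDs at least 2-fold apart in the same direction.

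The Xins well numbered 9 held reads of 17202 and 17197 IDs on the plates, beside medians of 4164 and 4205 in the other Xins wells. Greater read depth is argued against, since its 1990692 and 2531148 reads were below the medians of the others and thinning to 500000 reads left it at 3.69 times their median. RNA of X1 cells as the whole source is argued against too, since the X1-high set took at most 7.12% of its reads outside the dominant ID, beside 24.9% and 27% in X1 cells and medians of 4.78% and 4.71% in the other Xins wells. A small part from X1 cells stays open. Whether RNA of several cells was in the well stays open: its correlation with the sum of the other wells was 0.739 and 0.787, above the medians of 0.392 and 0.419 and the highest values of 0.478 and 0.483 of the others, but among the other wells this correlation followed the number of IDs (Spearman's rho 0.78 and 0.75), so it does not decide. No biological explanation was tested, as the labels set this well apart in no way, and without it the size rule gave 1037 IDs towards X1 and 1016 towards Xins.

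In the irradiated X1+X2 library the X1-high set was lower and the Xins-high set higher than in the X1 library. A smaller share of UMIs taken by the dominant ID makes every other ID higher, so it cannot account for the X1-high median of -1.04, which is -1.62 with that ID left out. It does not account for the Xins-high set as a whole, whose median was 1.22 with that ID left out. The wider gate and the irradiation cannot be told apart, because 0 further libraries combine the gate of one with the treatment of the other. Both stay open, as does any mixture of them.

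Of the 28 irradiated cells at the X1 library's level of the X1-high set, 25 fell in joint cluster 16 with 3 cells of the X1 library and 80 other irradiated cells, whose median X1-high share was 4.79%. The extent of this cluster depended on the seed: under 5 other seeds the cluster with 25 of the 28 held 45 to 58 irradiated cells. Doublets in equal parts with other irradiated cells would have an X1-high share near 16.2%, so the choice of the 28 by that share had already left them out, and their Xins-high shares, at most 8.62%, test nothing further. A small share of RNA from other irradiated cells stays open, although 96.4% of the 28 had an Xins-high share inside the 5% to 95% range of the X1 library. Their higher number of UMIs, a median of 27484 beside 16278 in the X1 library, stays open as a cause, since the depths gave unlike results. With at most 9000 UMIs per cell, a limit chosen after the result at 4000 was seen and reached by 27 of the 28 and by 93.3% of the X1 library, 2 of the 28 (7.14%) fell in clusters led by the X1 library and 25 together in another cluster, under each of 6 seeds. At 16000 UMIs 1 or 2 fell in clusters led by the X1 library. At 4000 UMIs the separation was lost, with 11 of the 28 in such clusters under 1 seed and all 28 under 5 others, while 0.69% to 1.98% of the other irradiated cells were in them, so the libraries were still told apart at that depth. Agreement with the clusters at full depth was low there, at an adjusted Rand index of 0.23 to 0.25. It was also low at 9000 UMIs, at 0.33 to 0.37, and was 0.58 to 0.63 at 16000 UMIs. The limit of 9000 was picked after the loss at 4000 and lies above the median of 8892 UMIs of the other irradiated cells. The number of UMIs therefore stays open as the cause, in whole or in part. A difference between the 2 libraries in preparation cannot be told apart from irradiation, since there was 1 irradiated library, and an effect of irradiation on these cells was not tested.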

How the results depend on the processing

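The alternatives that leave out the dominant ID, well 9, shallow wells or cells above 40000 UMIs, that thin the droplet cells to count IDs or to cluster them, or that concern the X1 level, the joint clusters and the matched plate cells were chosen after seeing the data. No paired analysis was possible because the numbers in the titles name cells, and the same number in 2 groups is no shared animal. Leaving cell cycle genes out of the clustering was not run, as no ID had a name. No cell filter and a 500 ID filter removed nothing and say nothing about stability, and leaving out called doublets removed 3 cells.

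Over 495 values of 62 results under an alternative, 314 stayed within the limit used for their kind of result, 177 moved beyond it without reversing, and 4 reversed. Of the values, 125 equalled the main value, among them those a setting could not move. The limit was a factor for counts, and the spread of the plates or a counting interval for others. For droplet folds and the plate correlation it was a small fixed difference. The totals therefore mix unlike limits. Except where stated, the cause was not tested. TMM and DESeq2 size factors gave 1133 and 1130 IDs towards X1 and 1016 and 1032 towards Xins.

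With the dominant ID left out, 1774 IDs lay towards X1, r of the plates was 0.827, 80.9% of IDs had the same sign, the X1-high set was read in a median of 65% of Mantis X1 cells, and the median log2 fold of all IDs with 1 CPM was 0.0613 on the Mantis plate in place of -0.26; this shift follows from the smaller totals. The 2 plates summed gave 1599 and 1894 IDs, and no filter on low IDs 1695 towards X1, as fewer conditions apply. The mean of CPM over cells gave r 0.851 and 81.5%, and a pseudocount of 10 CPM r 0.845. With no CPM minimum r was 0.623 with 69.4% of the same sign, and with 100 CPM 0.948 with 92.5%. Counting cells with 10 reads, the Xins-high set was found in a median of 27.5% and 32.5% of Xins cells, and after thinning in 30% and 35%. Thinning left X1 ahead of Xins by 1630 and 1726.5 IDs per cell, in place of 1852.5 and 1982, so depth limits these counts.

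The X1-high and Xins-high medians in the irradiated X1+X2 library against the X1 library kept their sign: -1.07 and 1.46 with the mean of CPM, -1.55 and 0.88 with median-of-ratios factors, -1.40 and 2.05 with a pseudocount of 1 CPM, -0.32 and 0.31 with 100 CPM, -0.96 and 1.10 in the mixed joint clusters, -1.62 and 1.22 without the dominant ID, and -1.02 and 1.34 without cells above 40000 UMIs. In the mixed clusters most X1 library cells lay in cluster 15 and most irradiated cells in cluster 11. The medians there therefore also compare different clusters. A higher pseudocount shrinks folds by construction. The median over all IDs reversed from 0.13 to -0.0798 with median-of-ratios factors and to -0.0508 without the dominant ID. The X1 library's lead of 803.5 IDs per cell reversed to -134 at 4000 UMIs and was 188.5 at 2000 UMIs outside the dominant ID. At the 1% point of the X1 library, 4.14% of irradiated cells reached its level.

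Resolution 2 gave 22 X1 clusters and thinning to 4000 UMIs 9. The irradiated share in joint clusters led by the X1 library was 0.19% with 15 components, 2.21% with 50, 2.02% with 1000 variable IDs and 2.31% after thinning to 4000 UMIs (3.37% to 4.62% under 5 other seeds). In matching plate cells to these clusters, 1000 variable IDs gave 85% of Mantis X1 cells, 1000 and 4000 variable IDs each gave 0% of Mantis Xins cells, 4000 variable IDs and Pearson correlation each gave 100% of Mantis X1 cells, and Pearson correlation gave 37.5% of ClonTechv4 and 12.5% of Mantis Xins cells.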

Other observations

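These values were chosen after the data were seen, and no test was run on them. The X1-high set was spread differently within the libraries than the Xins-high set. Of the 1051 measured Xins-high IDs, 55.9% had their highest mean in joint clusters led by the irradiated X1+X2 library and 41.3% in mixed clusters. No share over all measured IDs was computed to set beside these. Within mixed joint cluster 11, which held 28 X1 library and 147 irradiated cells, the median X1-high share was 8.16% in the former and 5.71% in the latter, and the Xins-high share 20.7% and 24.4%. In joint cluster 15, with 93 and 17 cells, the cells of the libraries lay far apart, at X1-high shares of 24.97% and 5.67%.

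Among the 28 irradiated cells at the X1 library's level of the X1-high set, the dominant ID took a median of 44.6% of the UMIs, beside 54.8% in the X1 library and 31.1% in the other irradiated cells. The 85 X1 library cells under 15% X1-high share had a median of 43.9%.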
